A study of Mus musculus with 15 samples.

How the data were processed

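Primary mouse brain microvascular endothelial cells from female animals aged 7 weeks were given fresh medium (NS), medium with TNF at 10 ng/ml, or medium with interleukin-1β at 20 ng/ml (IL1B) for 4 h, per the labels' protocols. Each of the 3 groups held 5 libraries, 15 in all, made from polyadenylated RNA with a stranded kit. Groups and library numbers were taken from the sample titles. Per the submitters' processing notes the tools were FastQC 0.11.2, TopHat2 2.0.13 and HTSeq 0.6.1 with the GRCm38 mouse genome, and the series' design text names DESeq2 for the authors' own comparison. The gene annotation, the strand setting of the counting and the treatment of reads shared between related genes are not given in the sources used here. The labels do not say whether the libraries of a group came from separate animals, so p-values measure the spread between these cultures.

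Each deposited table holds 1 normalised count per Ensembl gene for 1 library, per the labels and the table layout, with 47069 genes. The deposited normalised counts had lost their decimal point, so a cell gave the leading digits of a value and a power of 10 that carried no information. Within a library the non-zero values, 294623 in all, were written as whole multiples of 1 step, the value of 1 read, within the rounding of the last digit kept. At large read numbers that rounding lets any digits match, so a match of all values could not have failed. Between 98.7% and 99.3% of the non-zero values of a library matched a whole number under 10000 reads, against 0.965% to 1.63% of random digits. The inverse of the step is the size factor the authors divided by, and the 15 size factors lay within 0.139% of the median-of-ratios factors recomputed from the recovered reads over 15679 genes.

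A count and 10 times that count give the same digits, so trailing zeros were placed by likelihood. For each gene the placing took the 15 libraries together, with 1 level per group around the gene's own level (Student t on the natural-log scale, 2 degrees of freedom, scale 0.4) and a negative binomial spread averaged over 5 dispersions. Values of the other groups therefore enter the placing of a group's trailing zeros. This placing was chosen from simulated data after a placing within each group alone had been run and had given more false calls, and the older placing is kept as an alternative. Of the non-zero values 22272 (7.56%) were moved by a power of 10, 2.23% had a posterior under 0.95 and are called uncertain, and 99.66% were placed alike by both placings (1007 otherwise). The recovered reads per library ranged from 14742035 to 21392067 (median 17908946).

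The order of the genes in the deposited tables was not used in the recovery and gave a check of it. The tables came in 2 orders. Over the 14697 genes tested, the position in the NS tables had a Spearman correlation across genes of 0.982 with the unadjusted limma p of TNF against NS, and the position in the TNF and IL1B tables one of 0.982 with that of IL1B against TNF. With the 2 other comparisons the correlations lay between 0.236 and 0.655.

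The design fixed before the data were examined planned a count test on deposited counts. Because the deposited unit turned out to be a normalised count without its decimal point, that test was replaced with limma 3.58.1 (R 4.3.3) on log2(recovered normalised count + 1), a trended and robust empirical Bayes fit over all 15 libraries with the group as the only term. Genes with at least 10 recovered reads in at least 5 libraries were tested. Adjusted p-values are Benjamini-Hochberg values from that fit, and a gene was called at an adjusted p under 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. Values are given as mean ± SD of normalised reads over 5 libraries, and log2 fold changes ± SE. The recovery and plots used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

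Gene symbols and coordinates come from the GENCODE mouse annotation on GRCm38, which matched 46574 of the 47069 identifiers and left 495 unmatched, with 134 symbols shared by at least 2 identifiers. The genes named per comparison were fixed by rule: Ackr1, the 10 called genes with the highest and the 10 with the lowest log2 fold change among those with a mean of at least 5 CPM (counts scaled to the library's total) in the higher group, no overlap between the libraries of both groups and a symbol that is not a Gm number, a Rik clone name, a pseudogene or a bare identifier, up to 2 called members with the largest rise and 2 with the largest fall of each list (in a list with no call, the 2 members with the largest mean), and, against NS, 11 adhesion, junction and caveolar genes. Genes named outside the rule are said to be so, and the results of some genes within it are not reported.

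The 29 gene lists and 11 marker lists were fixed before the data were examined. Of the marker lists 9 could be tested, since 1 of 8 choroid plexus and epithelial markers and 0 of 5 red blood cell markers were among the genes tested, so for those lists only sums are given. Each of the other lists was tested with camera (preset inter-gene correlation 0.01), again with an estimated correlation, and with fry, and the p-values were adjusted over the lists of a comparison. Calls of members were counted over all genes tested and adjusted over the list alone. Where no second count is given, both counts were equal.

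Libraries with the same number carry the same code in their descriptions, and the numbers were checked as pairs. After the group means were removed, all 15 same-numbered pairs of libraries correlated across genes at r over 0.1 (0.119 to 0.443, median 0.307), while pairs with other numbers ranged from −0.372 to 0.341, and 13 of the 15 libraries matched best with their own number in another group. With the trailing zeros placed within each group alone, 14 of the 15 pairs lay over 0.1 and the lowest was 0.0816. The numbers were therefore taken to pair the samples, and a fit with the replicate number as a block was run. The SE, adjusted p, counts and list tests below come from the fit without the block, unless the block is named. That fit leaves the differences between pairs in the error. For TNF against NS it called 3364 genes, against 5349 with the block. No 2 replicates agreed within sampling noise, with a chi-square per gene between 2.99 (NS 4 and NS 5) and 51.2 (IL1B 1 and IL1B 5).

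The scripts were tested on simulated data. The placing was chosen on 1 draw and assessed on 3 fresh draws, in which NS and TNF had the NS means apart from 200 changed genes per draw, IL1B had its own means, and the decimal point was lost as in the deposited tables. There, 99.61% of 888038 non-zero values were recovered (92.34% without placing trailing zeros). Over a mean of 14731 genes, 62.8% of the genes changed 1.5-fold were called (135 of 215), 85.7% of those changed 2-fold (162 of 189) and 93.4% of those changed 4-fold (183 of 196). Of 515 calls 35 (6.80%) were false, against 20 of 498 (4.02%) on the values as drawn, so the false share of the recovered values lay somewhat above the threshold set. Of the simulated IL1B values of 408 genes with a difference of at least 4-fold, 98.19% were recovered. The levels and the spread of the draws came from the recovered reads, whose trailing zeros this placing had set. The draws held no pairs and no library that stood apart, so the shares may be too favourable for the real libraries.

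The alternatives were TMM scaling, no filter, a stricter filter (5 CPM in 5 libraries), the replicate block, a fit to only both groups compared, a test against a 1.5-fold change (limma treat), and leaving out each library in turn. Added after the data were seen were library-total scaling, pseudocounts of 0.5 and 5, limma voom on the recovered reads, trailing zeros placed within each group alone, leaving out the moved and uncertain values, and the libraries numbered 2, 4 and 5 alone.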

Results

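Polyadenylated RNA was sequenced from primary mouse brain microvascular endothelial cells, which line the small vessels of the brain and form the blood-brain barrier, after 4 h in fresh medium (NS), in medium with 10 ng/ml TNF or in medium with 20 ng/ml interleukin-1β (IL1B). Each group had 5 libraries of 14742035 to 21392067 recovered reads, and 14697 genes were tested. The first principal component (56.5% of the variance) placed the NS libraries between −54.4 and −42.2, the TNF libraries between −18.2 and 7.40 and the IL1B libraries between 22.9 and 63.2, so the groups did not overlap. IL1B replicate 5 lay at 22.9 and the other IL1B libraries between 56.4 and 63.2. On the second component (9.93%) the libraries numbered 1 and 3 of every group lay between 12.9 and 27.8 and those numbered 2, 4 and 5 between −26.5 and −2.37. The libraries numbered 1 and 3 also held larger sums of pericyte and smooth muscle markers, 1446 and 969 counts scaled to the library's total (CPM) in NS against 314 to 354 in the other NS libraries, 1497 and 865 against 257 to 364 with TNF, and 1509 and 1015 against 268 to 420 with IL1B. Their fibroblast marker sums were 324 and 452 CPM in NS against 65.6 to 91.4, 249 and 173 against 52.7 to 94.1 with TNF, and 159 and 224 against 73.5 to 90.3 with IL1B.

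The unstimulated cells carried a strong endothelial profile. Summed over the endothelial markers, the NS libraries held 18820 ± 873 CPM (SD, n = 5), against 681 ± 509 for pericyte and smooth muscle markers, 204 ± 174 for fibroblast and 87.3 ± 11.6 for astrocyte markers. The NS sums were 62.2 ± 7.54 for choroid plexus and epithelial, 44.2 ± 2.26 for microglial and macrophage, 30.8 ± 1.31 for oligodendrocyte, 3.82 ± 1.15 for neuronal, 2.74 ± 1.00 for lymphocyte and 0.448 ± 0.194 for red blood cell markers. The endothelial sum was 15190 ± 1713 with TNF and 11770 ± 1754 with IL1B. The pericyte and smooth muscle sum was 655 ± 531 with TNF and 723 ± 526 with IL1B, and the choroid plexus and epithelial sum 37.0 ± 8.89 and 22.4 ± 8.30. Of the choroid plexus and epithelial markers only Clic6 passed the filter of the genes tested, so that sum need not follow a number of cells. Mitochondrially encoded transcripts summed to 16200 ± 487 in NS, 15840 ± 636 with TNF and 14700 ± 924 with IL1B, and none of the 13 was called in any comparison with the deposited size factors. With library-total scaling mt-Cytb was called lower with IL1B than in NS (−0.15, adjusted p = 0.0442).

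The first comparison asked which transcripts TNF changed within 4 h, with Ackr1, the receptor of the series title, first. Ackr1 (ENSMUSG00000037872, minus strand of chromosome 1, 173331886 to 173333750) encodes an atypical receptor that binds chemokines and carries them across endothelium without classical signalling. It rose from 84.5 ± 18.7 normalised reads in NS to 848 ± 159 with TNF (SD, n = 5), 10.0-fold (log2 fold change 3.32 ± 0.19, SE, limma adjusted p = 1.79e-08). The adhesion molecules that capture leukocytes on endothelium rose with it: P-selectin (Selp) 36.5-fold, E-selectin (Sele) 17.5-fold, Icam1 10.6-fold and Vcam1 7.17-fold. Of the junction genes, Cldn5 (log2 fold change −0.13, adjusted p = 0.637) and Cdh5 (−0.01, adjusted p = 0.919) did not pass the test, nor did Cav1 of the caveolae (−0.02, adjusted p = 0.873), while the tight junction gene Ocln fell by 0.42 on the log2 scale (adjusted p = 0.0425).

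In all, 1837 genes were higher and 1527 lower with TNF than in NS (Benjamini-Hochberg adjusted p under 0.05), 317 and 212 of them by at least 2-fold. Called genes were 22.9% of those tested, the share against which counts of called list members are to be read. For 2784 genes (18.9%) the 5 TNF and 5 NS libraries did not overlap, where chance gives 0.794%. Higher genes were 54.6% of the calls, and 46.2% when values were scaled by library totals, which gave 1554 higher and 1813 lower. With the replicate number as a block 2702 genes were higher and 2647 lower.

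Among genes with at least 5 CPM in the higher group and no overlap between the libraries of both groups, the largest rises with TNF were those of Acod1, the enzyme that makes itaconate (11.6 ± 5.65 normalised reads in NS, 581 ± 186 with TNF, log2 fold change 5.58 ± 0.35), Selp (chromosome 1, 164115264 to 164150026; 22.7 ± 12.6 and 940 ± 538, 5.19 ± 0.46), and the T-cell chemokine gene Cxcl10 (14.3 ± 8.95 and 271 ± 122, 4.28 ± 0.48). Next came Sele, which neighbours Selp (chromosome 1, 164048234 to 164057677; 142 ± 94.8 and 2753 ± 1741, 4.13 ± 0.64), and Icosl, the ligand of a T-cell costimulatory receptor (61.1 ± 17.8 and 888 ± 290, 3.81 ± 0.25). Within these limits they were followed by Apol7c (3.58 ± 0.43), Heatr3 (3.57 ± 0.09), the Rap effector gene Radil (3.55 ± 0.36), Icam1 (chromosome 9, 21015985 to 21028817; 2942 ± 956 and 31230 ± 9084, 3.41 ± 0.28) and the neutrophil chemokine gene Cxcl2 (3.38 ± 0.31). Their limma adjusted p ranged from 4.59e-14 (Heatr3) to 0.000409 (Sele).

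Among the largest falls with TNF within the same limits were those of Tril, an accessory protein of Toll-like receptors (241 ± 59.9 normalised reads in NS, 49.9 ± 61.3 with TNF, log2 fold change −2.88 ± 0.65), Ripor2 (−2.26 ± 0.33) and Cyp26b1, which degrades retinoic acid (−2.01 ± 0.50). The cadherin gene Cdh26, the potassium channel gene Kcnj2 (−1.75 ± 0.35), the microtubule-severing gene Fign (−1.73 ± 0.39), the barrier transporter gene Slco1a4 (7872 ± 2260 and 2463 ± 933, −1.71 ± 0.39) and the ganglioside synthase gene St3gal5 (−1.68 ± 0.16) were also among them. Their adjusted p ranged from 1.11e-06 (Cdh26) to 0.00935 (Cyp26b1). The call of Tril depended on the placing of trailing zeros in 4 uncertain values: with zeros placed within each group alone its log2 fold change was −0.93 (adjusted p = 0.255), and with the moved and uncertain values left out −1.60 (adjusted p = 0.162).

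All 19 NF-kappaB pathway and feedback genes called among 24 rose with TNF, among them the inhibitor genes Nfkbie (2.18 ± 0.15) and Tnfaip3 (2.07 ± 0.24), and 21 rose adjusted over the list alone. NF-kappaB genes had a camera adjusted p = 1.49e-20. Of 23 genes of MHC class I presentation 21 rose and none fell, led by H2-Q6 (2.35) and H2-Q7 (2.04). MHC class I genes had a camera adjusted p = 4.45e-23. H2-Q6 and H2-Q7 are near-identical copies, and their single values are uncertain because the counting of shared reads is not given in the sources used here, as is that of Gbp6 among its close relatives. Of 40 interferon-induced genes 27 rose and none fell, with Zbp1 (3.16) and Gbp6 (2.53) in front, or 30 and 1 adjusted over the list alone. Interferon-induced genes had a camera adjusted p = 1.70e-18. Chemokines rose in 11 of 17 and fell in none, among them Cxcl10 and Ccl5 (3.51). Chemokines had a camera adjusted p = 1.01e-08. Of the 15 values of Ccl5 8 were uncertain in their trailing zeros, its log2 fold change was 1.55 with zeros placed within each group alone, and limma voom did not call it (adjusted p = 0.184), nor did the libraries numbered 2, 4 and 5 alone (adjusted p = 0.148). Costimulatory and coinhibitory ligands rose in 8 of 11, led by Icosl and Tnfsf4 (2.33), and none fell. Costimulatory ligands had a camera adjusted p = 4.44e-06. Cytokines and colony-stimulating factors rose in 8 of 19, with Csf2 (3.70) and Lif (3.29) in front, and in 11 adjusted over the list alone, while none fell. Cytokines had a camera adjusted p = 7.25e-06. Leukocyte adhesion molecules rose in 8 of 15 and fell in 1, Cd99l2 (−0.28). Leukocyte adhesion molecules had a camera adjusted p = 0.000133. Cell death regulators rose in 7 of 17, among them the pore-forming Gsdmd (1.67) and the pro-apoptotic Bid (1.65), and fell in 1, the survival gene Mcl1 (−0.19), or 2 adjusted over the list alone. The call of Mcl1 was lost without NS replicate 2 or 5 or TNF replicate 4 (adjusted p = 0.0528 to 0.0638) and with the libraries numbered 2, 4 and 5 alone (adjusted p = 0.0654). Cell death regulators had a camera adjusted p = 0.00204. These 8 lists also passed with an estimated correlation, at adjusted p = 0.0273 to 0.0376.

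Of 29 blood-brain barrier transporters 9 fell with TNF, led by Slco1a4, and 3 rose, including the lipid transporter gene Mfsd2a (1.24 ± 0.29), or 12 and 3 adjusted over the list alone. Barrier transporters had a camera adjusted p = 0.00687, and adjusted p = 0.0323 with an estimated correlation. Of the 21 genes of the Wnt and beta-catenin barrier programme 9 fell, among them the Wnt transcription factor gene Tcf7 (−1.07) and Tnfrsf19 (−0.94), and 1 rose, Sox7 (0.42), or 13 and 1 adjusted over the list alone. Wnt genes had a camera adjusted p = 2.52e-05, and adjusted p = 0.227 with an estimated correlation. Notch pathway genes fell in 5 of 15, led by Lfng (−1.67), and rose in 1, Notch2 (0.59). Notch genes had a camera adjusted p = 0.00991, and adjusted p = 0.252 with an estimated correlation. Cell cycle genes fell in 6 of 27, all of them genes of the Mcm helicase such as Mcm2 (−0.58), and none rose. Cell cycle genes had a camera adjusted p = 0.0120, and adjusted p = 0.626 with an estimated correlation and 0.245 with fry. Sterol synthesis genes rose in 7 of 19, led by Hmgcs1 (0.67) and Mvd (0.65), or 9 adjusted over the list alone, and fell in 1, Mvk (−0.46). Sterol genes had a camera adjusted p = 0.00666, and adjusted p = 0.494 with an estimated correlation and 0.0583 with fry. The venous endothelial markers, which share Ackr1, Selp, Vcam1 and Icam1 with the immune genes above, rose in 5 of 14 and fell in 3, or 6 and 3 adjusted over the list alone. Venous endothelial markers had a camera adjusted p = 0.0204, adjusted p = 0.0989 with an estimated correlation, and adjusted p = 0.150 with the replicate block.

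The other lists did not pass camera with TNF (adjusted p = 0.0513 to 0.837). Tight and adherens junction genes fell in 7 of 22 and rose in 2, with Jup (−0.68) and F11r (0.51) at the ends, angiogenic receptors and ligands fell in 8 of 20 and rose in 3, and arterial markers fell in 2 of 14. With the replicate block these 3 lists passed (adjusted p = 0.0253, 0.0286 and 0.0298), against adjusted p = 0.494, 0.252 and 0.252 with an estimated correlation. Counts of rises and falls were 2 and 2 of 7 for chemokine receptors, 3 and 6 of 22 for caveolae and vesicle transport and 6 and 3 of 27 for actin and transendothelial migration machinery (7 and 6 adjusted over the list alone). For signalling and antigen presentation they were 4 and 1 of 19 for TNF receptor signalling, 3 and 0 of 15 for IL-1 receptor signalling, and 1 and 0 of 4 for MHC class II presentation. They were 3 and 2 of 10 for complement (4 and 2 adjusted over the list alone), 3 and 2 of 19 for coagulation and fibrinolysis, 4 and 0 of 14 for prostaglandin and nitric oxide synthesis (6 and 1 adjusted over the list alone), 4 and 2 of 22 for matrix and matrix proteases. The last lists had 7 and 3 of 23 for immediate early genes (7 and 5 adjusted over the list alone) and 2 and 0 of 15 for endoplasmic reticulum stress. The median and the mean log2 fold change differed in sign for chemokine receptors (−0.12 and 0.34, test upward), coagulation (−0.05 and 0.04, test downward) and endoplasmic reticulum stress (−0.03 and 0.07, test upward).

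Endothelial markers fell in 7 of 15 with TNF and rose in none (camera adjusted p = 0.00125 over the marker lists, and adjusted p = 0.832 with an estimated correlation). Pericyte and smooth muscle markers fell in 2 of 12 (1 adjusted over the list alone), Anpep and Pdgfrb. Anpep was not called without the low-count filter (adjusted p = 0.0818) or without NS replicate 1, 2, 3 or 4 (adjusted p = 0.0718 to 0.132). Pdgfrb was not called without NS replicate 1 or 2 (adjusted p = 0.0553 and 0.0527). Among 5 astrocyte markers 1 gene rose, Slc1a3 (2.27). Among 3 microglial and macrophage markers 1 rose, Aif1. Aif1 was not called without TNF replicate 2 or 3 (adjusted p = 0.0548 and 0.0534) or with the libraries numbered 2, 4 and 5 alone (adjusted p = 0.111). None of the 9 fibroblast, 2 oligodendrocyte, 3 neuronal and 2 lymphocyte markers was called without the replicate block. With it the neuronal markers Tubb3 (0.66, adjusted p = 0.028) and Nefm (−0.95, adjusted p = 0.0311) were. The call of Ocln was lost without the low-count filter (adjusted p = 0.0648) and with the moved and uncertain values left out (adjusted p = 0.0859). It was also lost without NS replicate 1, 2, 4 or 5 or TNF replicate 1, 2 or 3 (Ocln adjusted p = 0.0579 to 0.105) and with the libraries numbered 2, 4 and 5 alone (adjusted p = 0.163). Pecam1 (−0.21), Tjp1 (−0.16) and Plvap (−0.45) were called only with the replicate block (adjusted p = 0.0373, 0.0142 and 0.000343, against 0.303, 0.347 and 0.136 without it).

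**Figure D1:**
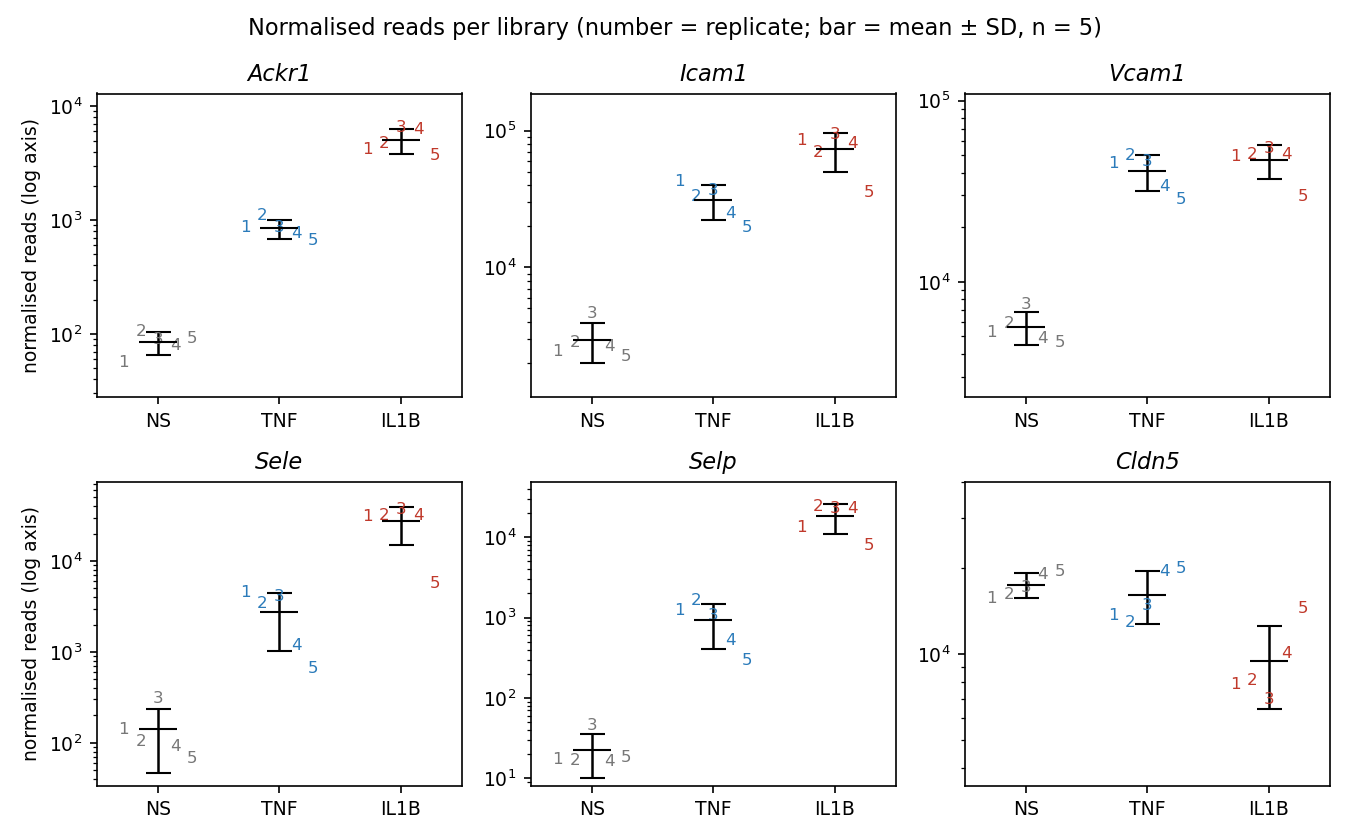
Normalised reads per library (log axis) of Ackr1, 4 adhesion molecule genes and the junction gene Cldn5 in the NS, TNF and IL1B groups. Digits mark the library number, and bars give the mean ± SD of 5 libraries. Ackr1 had means of 84.5, 848 and 5069, and Cldn5 of 17480, 16160 and 9480.

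The second comparison asked the same of IL1B. Ackr1 rose to 5069 ± 1254 normalised reads (SD, n = 5), 59.1-fold over NS (log2 fold change 5.88 ± 0.19, SE, limma adjusted p = 2.28e-11). Selp rose 772-fold to 18270 ± 7292, Sele 186-fold to 27200 ± 12290, Icam1 24.3-fold to 72860 ± 22790 and Vcam1 8.27-fold to 46940 ± 9964. Csf2, Csf3, Ccl20, Cxcl3 and Il6, scarce in NS, reached much higher levels. Lower were Cldn5 at 17480 ± 1705 in NS and 9480 ± 3029 with IL1B (−0.93 ± 0.18, adjusted p = 0.000366), Ocln (−0.74 ± 0.14, adjusted p = 0.000338) and the platelet-endothelial adhesion molecule gene Pecam1 (−0.74 ± 0.14, adjusted p = 0.000257), whereas Cdh5 (−0.08, adjusted p = 0.430) and Cav1 (−0.10, adjusted p = 0.230) did not pass.

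In all, 4147 genes were higher and 4111 lower with IL1B than in NS, 749 and 1014 of them by at least 2-fold, and for 5755 genes (39.2%) the libraries of both groups did not overlap (chance 0.794%). Called genes were 56.2% of those tested. A count of called list members near or under that share, as for the cell cycle genes below, does not by itself set a list apart. Higher genes were 50.2% of the calls, and 33.3% when values were scaled by library totals, which moved the median log2 fold change of all genes to −0.15 and gave 2807 genes higher and 5631 lower. With that scaling Tjp1 (−0.36, adjusted p = 0.0214), Cdh5 (−0.23, adjusted p = 0.0307) and Cav1 (−0.25, adjusted p = 0.00604) were also called lower, and with the replicate block Tjp1 (−0.21, adjusted p = 0.00112) and Plvap (−0.32, adjusted p = 0.00233) were, against adjusted p = 0.141 and 0.201 without it.

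Among genes with at least 5 CPM in the higher group and no overlap between the libraries of both groups, the 10 largest rises with IL1B were those of the colony-stimulating factor genes Csf2 (1.79 ± 3.06 normalised reads in NS, 2846 ± 861 with IL1B, log2 fold change 10.43 ± 0.65) and Csf3 (7.81 ± 1.68 and 6364 ± 2735, 9.32 ± 0.42), the chemokine genes Ccl20 (0.911 ± 1.08 and 2431 ± 1874, 9.84 ± 0.84), Cxcl3 (9.33 ± 0.25), Cxcl2 (51.1 ± 17.6 and 25760 ± 6748, 8.96 ± 0.31) and Cxcl1 (197 ± 51.6 and 73370 ± 27820, 8.45 ± 0.34). The others were Selp (9.59 ± 0.46), the metalloreductase gene Steap4 (9.29 ± 0.56), the retinol receptor gene Stra6 (8.72 ± 0.35) and Il6 (3.90 ± 3.08 and 1198 ± 400, 8.10 ± 0.50). Their adjusted p ranged from 1.29e-13 (Cxcl3) to 3.01e-07 (Ccl20). Cxcl3, Cxcl1 and Cxcl2 lie together on chromosome 5 (from 90786103, the start of Cxcl3, to 90905938, the end of Cxcl2). Of the 15 values of Ccl20 7 were uncertain in their trailing zeros, as were 5 of Csf2.

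Among the largest falls with IL1B within the same limits were those of Tril (−6.08 ± 0.65), Ripor2 (301 ± 59.9 normalised reads in NS, 13.7 ± 6.21 with IL1B, −4.44 ± 0.33), the lactate receptor gene Hcar1 (−3.71 ± 0.31) and Tmem44 (2164 ± 357 and 179 ± 67.6, −3.68 ± 0.32). Then came the actin-binding gene Ablim1 (22830 ± 2742 and 1949 ± 596, −3.61 ± 0.25), Fign (−3.47 ± 0.39), Slco1a4 (7872 ± 2260 and 779 ± 340, −3.47 ± 0.39), the mineralocorticoid receptor gene Nr3c2 (−3.25 ± 0.38) and the actin-capping gene Eps8 (−3.08 ± 0.34). Their adjusted p ranged from 3.24e-08 (Ablim1) to 5.17e-06 (Nr3c2).

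Among the immune lists, 22 of 24 NF-kappaB pathway genes rose with IL1B and none fell, led by Tnfaip2 (4.09) and the atypical inhibitor gene Nfkbiz (3.57). NF-kappaB genes had a camera adjusted p = 4.28e-13, and adjusted p = 0.103 with an estimated correlation. Interferon-induced genes rose in 34 of 40, with the antiviral Mx1 (4.16) and Gbp6 (4.02) in front, and fell in 1, Irf8 (−0.51; adjusted p = 0.0545 without IL1B replicate 3). Interferon-induced genes had a camera adjusted p = 8.40e-11, and adjusted p = 0.138 with an estimated correlation. MHC class I presentation rose in 19 of 23 and fell in none, with H2-Q6 (2.26) highest. MHC class I genes had a camera adjusted p = 3.14e-10, and adjusted p = 0.136 with an estimated correlation. Chemokines rose in 13 of 17 and fell in none, or in 1 adjusted over the list alone. Chemokines had a camera adjusted p = 1.17e-07, and adjusted p = 0.103 with an estimated correlation. Cytokines and colony-stimulating factors rose in 14 of 19 and fell in none, or in 1 adjusted over the list alone. Cytokines had a camera adjusted p = 4.15e-07, and adjusted p = 0.0573 with an estimated correlation. Costimulatory and coinhibitory ligands rose in 8 of 11, led by Tnfsf15 (7.69) and Icosl (6.29), and fell in none, or in 1 adjusted over the list alone. Costimulatory ligands had a camera adjusted p = 0.000367, and adjusted p = 0.103 with an estimated correlation. Leukocyte adhesion molecules rose in 10 of 15 and fell in 2, Pecam1 and Cd99l2 (−0.52). Leukocyte adhesion molecules had a camera adjusted p = 0.00632, and adjusted p = 0.136 with an estimated correlation.

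Cell death regulators rose in 11 of 17, led by the inflammasome sensor gene Nlrp3 (7.91) and Bid (2.18), and fell in 3, Bcl2 (−1.03), Bbc3 (−0.46) and Mcl1. Cell death regulators had a camera adjusted p = 0.0171, and adjusted p = 0.103 with an estimated correlation. Prostaglandin and nitric oxide synthesis rose in 8 of 14, with the inducible nitric oxide synthase gene Nos2 (3.82) and the prostaglandin synthase gene Ptges (3.20), and fell in 2, the endothelial nitric oxide synthase gene Nos3 (−0.84) and Ptgis (−0.59). Prostaglandin and nitric oxide genes had a camera adjusted p = 0.0171, and adjusted p = 0.268 with an estimated correlation. TNF receptor signalling components rose in 9 of 19, led by the death receptor gene Fas (3.66), and fell in 3. TNF receptor signalling genes had a camera adjusted p = 0.0493, and adjusted p = 0.274 with an estimated correlation.

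Of the barrier lists, 15 of 21 genes of the Wnt and beta-catenin barrier programme fell with IL1B, led by Tnfrsf19 (−2.38) and Tcf7 (−2.26), and 1 rose, Sox7 (0.83), or 16 and 1 adjusted over the list alone. Wnt genes had a camera adjusted p = 8.69e-05, and adjusted p = 0.268 with an estimated correlation. Blood-brain barrier transporters fell in 15 of 29 and rose in 6, among them Mfsd2a (2.03) and the efflux pump gene Abcc1 (1.55), or 16 and 6 adjusted over the list alone. Barrier transporters had a camera adjusted p = 0.0493, and adjusted p = 0.136 with an estimated correlation. Tight and adherens junction genes fell in 11 of 22, led by Jup (−1.32) and Cldn5, and rose in 5, led by Cldn1 (1.10) and F11r (0.66). Junction genes had a camera adjusted p = 0.0451, and adjusted p = 0.443 with an estimated correlation. Notch pathway genes fell in 10 of 15, led by Lfng (−2.50) and Jag2 (−1.47), and rose in 2, Notch2 (0.53) and Jag1 (0.38), or 3 adjusted over the list alone. Notch genes had a camera adjusted p = 0.0171, and adjusted p = 0.275 with an estimated correlation. Jag1 was not called with library-total scaling (adjusted p = 0.106) or without IL1B replicate 4 (adjusted p = 0.0517). Cell cycle genes fell in 6 of 27, again Mcm genes such as Mcm2 (−1.15), and rose in 1, Pcna (0.27), which was not called with library-total scaling (adjusted p = 0.271), without NS replicate 1 or IL1B replicate 2, 3 or 4 (Pcna adjusted p = 0.0587 to 0.0708) or with the libraries numbered 2, 4 and 5 alone (adjusted p = 0.130). Cell cycle genes had a camera adjusted p = 0.0171, and adjusted p = 0.607 with an estimated correlation and 0.0547 with fry.

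The other lists did not pass camera with IL1B (adjusted p = 0.0510 to 0.924). Caveolae and vesicle transport genes fell in 9 of 22, led by the caveolar coat gene Cavin2 (−2.75), and rose in 5, led by Ehd1 (1.33). Actin and transendothelial migration machinery rose in 14 of 27, led by Src, and fell in 7, led by the filamin-interacting gene Filip1 (−1.71) and Ezr (−1.15). Matrix and matrix proteases rose in 9 of 22, led by Mmp13 (5.27) and Mmp3 (3.84), and fell in 4. Immediate early genes rose in 10 of 23 and fell in 5, and arterial markers fell in 6 of 14 and rose in 1, Tm4sf1 (0.89). With the replicate block these last 3 lists passed (adjusted p = 0.0440 for matrix and for immediate early genes and 0.0358 for arterial markers), against adjusted p = 0.322, 0.457 and 0.275 with an estimated correlation. Counts of rises and falls were 2 and 2 of 7 for chemokine receptors, with Ackr1 and Ccrl2 (2.61) higher and the scavenging receptor genes Ackr2 (−2.35) and Ackr4 (−2.30) lower. Vessel type and receptor lists had 5 and 5 of 14 for venous markers, 4 and 12 of 20 for angiogenic receptors and ligands, with the VEGF receptor gene Kdr at −1.53, and 8 and 3 of 15 for IL-1 receptor signalling, led by the inhibitor gene Irak3 (2.99) (9 and 3 adjusted over the list alone). They were 1 and 1 of 4 for MHC class II presentation, 4 and 2 of 10 for complement, led by C3 (4.92), 9 and 6 of 19 for coagulation and fibrinolysis, 7 and 1 of 15 for endoplasmic reticulum stress, and 7 and 2 of 19 for sterol synthesis (6 and 2 adjusted over the list alone). The median and mean log2 fold change differed in sign for chemokine receptors (−0.08 and 0.52, test upward), MHC class II (−0.09 and 0.32, test downward) and venous markers (−0.09 and 1.90, test upward).

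Endothelial markers fell in 12 of 15 with IL1B, or 13 adjusted over the list alone, and rose in none (camera adjusted p = 0.000182 over the marker lists, and adjusted p = 0.843 with an estimated correlation). Their log2 fold changes reached from −3.47 (Slco1a4) to −0.08 (Cdh5, not called). Astrocyte markers rose in 2 of 5, Slc1a3 (2.65) and the gap junction gene Gja1 (0.86), and their sum was 141 ± 10.8 CPM with IL1B and 87.3 ± 11.6 in NS. Pericyte and smooth muscle markers fell in 3 of 12 (2 adjusted over the list alone), 1 of 9 fibroblast markers rose (0 adjusted over the list alone), Dcn (0.86), 1 of 3 microglial markers rose and 1 fell, with a test downward against a median of 0.20 and a mean of 0.15. The microglial marker that rose, Cd68, was not called without NS replicate 3 or 5 or IL1B replicate 1, 2 or 4 (adjusted p = 0.0554 to 0.0830), with library-total scaling (adjusted p = 0.0690), with the moved and uncertain values left out (adjusted p = 0.0824) or with the libraries numbered 2, 4 and 5 alone (Cd68 adjusted p = 0.190). Of the other markers 1 of 2 oligodendrocyte and 1 of 2 lymphocyte markers fell, and none of 3 neuronal markers was called. The lymphocyte marker, Cd79a, was not called without NS replicate 2 (adjusted p = 0.0598).

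**Figure D2:**
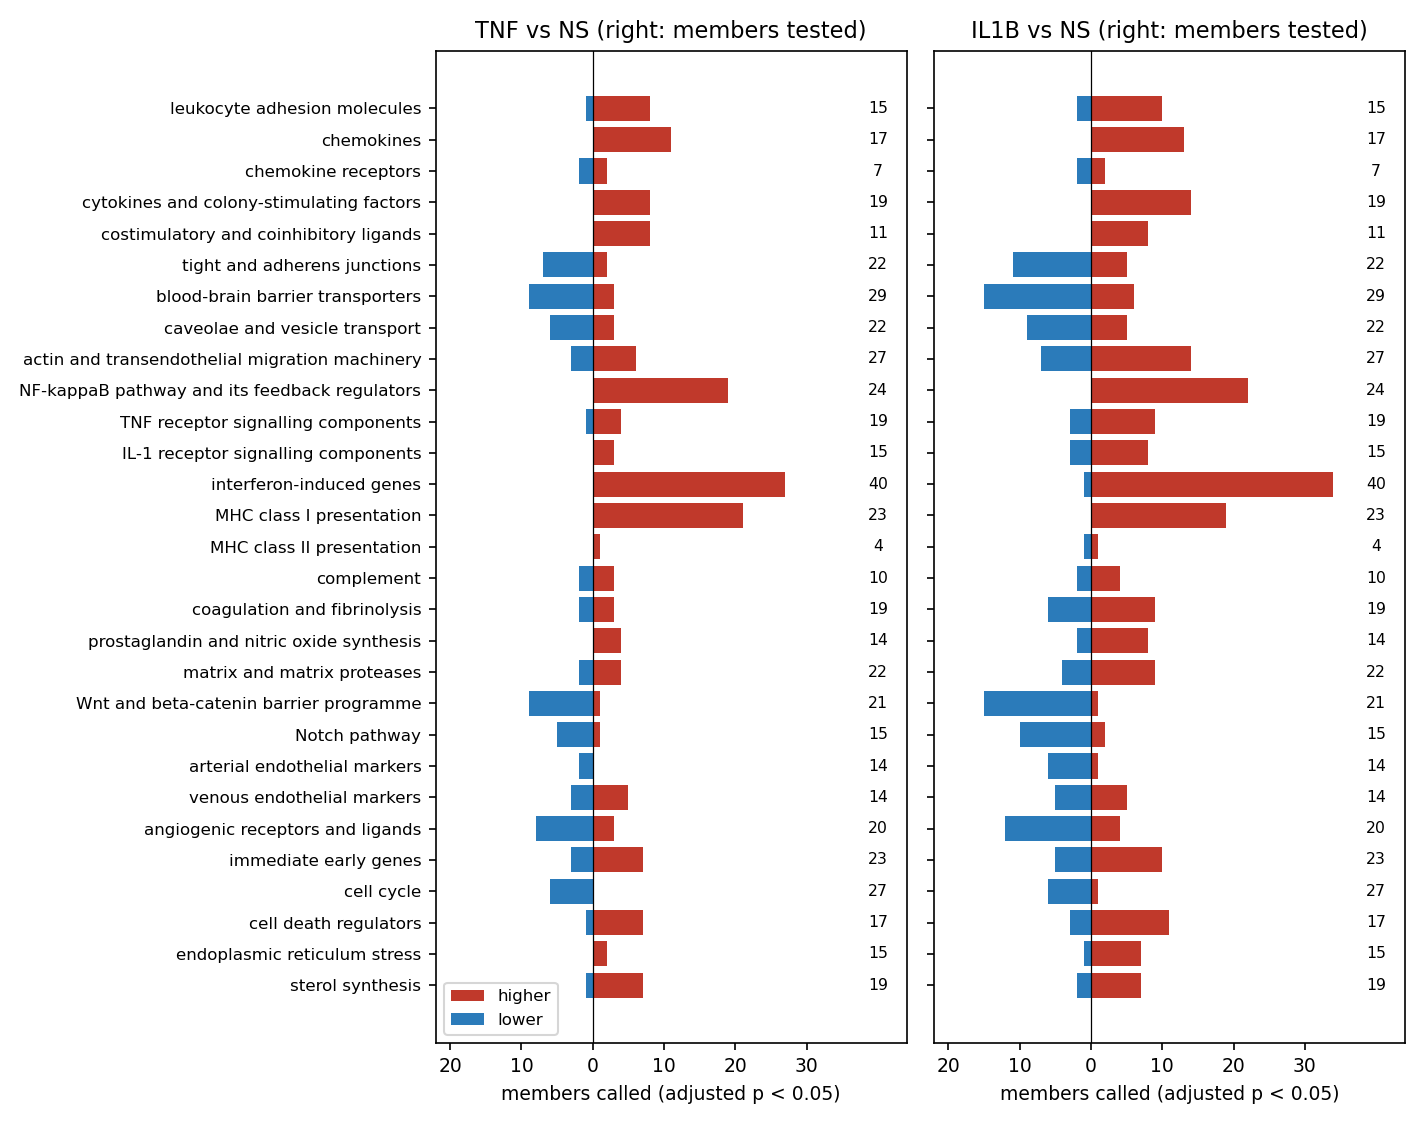
Members of the 29 gene lists called higher (red, to the right) or lower (blue, to the left) with TNF and with IL1B, as counts of genes with limma adjusted p under 0.05, and the number of members tested at the right edge. With IL1B 34 of 40 interferon-induced genes were higher and 15 of 21 genes of the Wnt and beta-catenin barrier programme lower.

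The third comparison set IL1B against TNF directly. Ackr1 was 5.91-fold higher with IL1B (log2 fold change 2.56 ± 0.19, SE, limma adjusted p = 4.16e-07, n = 5 per group), and Selp (4.40), Sele (3.41) and Icam1 were higher too, whereas Vcam1 did not differ beyond the test. Within the limits on level and overlap given above, the 10 genes furthest above TNF were 99.3-fold (Shisa3) to 508-fold (Csf3) higher with IL1B. Slco2b1, Slco1a4 and Pnpla7 were lower, as was Cldn5 (−0.80, adjusted p = 0.00373).

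In all, 2358 genes were higher and 2352 lower with IL1B than with TNF, 285 and 257 of them by at least 2-fold, and for 1896 genes (12.9%) the libraries did not overlap (chance 0.794%). Called genes were 32.0% of those tested, the share against which the list counts below are to be read. Higher genes were 50.1% of the calls. With library-total scaling 1344 were higher and 3701 lower, 26.6% of the calls higher, and the median log2 fold change of all genes moved to −0.11. With the replicate block 3342 were higher and 3397 lower.

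Among genes with at least 5 CPM in the higher group and no overlap between the libraries of both groups, the 10 furthest above TNF were Csf3 (6364 ± 2735 normalised reads with IL1B, log2 fold change 8.99 ± 0.42), Ccl20 (8.31 ± 12.4 and 2431 ± 1874, 8.20 ± 0.84), Il19 (556 ± 153 with IL1B, 7.94 ± 0.47), Il6 (5.33 ± 3.88 and 1198 ± 400, 7.76 ± 0.50), Nlrp3 (2.36 ± 1.61 and 512 ± 114, 7.35 ± 0.37). Next were Cxcl3 (7.29 ± 0.25), Steap4 (6.98 ± 0.56), Cxcl5, which lies beside Cxcl3 on chromosome 5 (6.95 ± 0.66), Csf2 (6.73 ± 0.65) and Shisa3 (6.63 ± 0.39). Their adjusted p was at most 1.46e-05 (Ccl20), and 8 of the 15 values of Cxcl5 were uncertain in their trailing zeros. Within the same limits the 10 furthest below were Ablim1 (11030 ± 3625 and 1949 ± 596, −2.51 ± 0.25), the organic anion transporter gene Slco2b1 (5862 ± 1852 and 1256 ± 593, −2.32 ± 0.36), Tmem44 (−2.31 ± 0.32), the lysophospholipase gene Pnpla7 (−1.86 ± 0.34) and Slco1a4 (−1.76 ± 0.39). The rest were Rasgef1a (959 ± 125 and 297 ± 115, −1.75 ± 0.21), the transcriptional repressor gene Bach2 (−1.73 ± 0.27), the sphingolipid exporter gene Spns2 (1608 ± 341 and 536 ± 284, −1.68 ± 0.24), Gnb4 (−1.56 ± 0.41) and Neurl1b, a ubiquitin ligase of Notch ligands (−1.54 ± 0.23). Their adjusted p ranged from 9.95e-06 (Ablim1) to 0.0108 (Gnb4), and Gnb4 was not called with zeros placed within each group alone (−0.90, adjusted p = 0.0536).

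Of the lists, chemokines were higher with IL1B than with TNF in 11 of 17 and lower in none, or 13 and 1 adjusted over the list alone. Chemokines had a camera adjusted p = 4.56e-07, and adjusted p = 0.156 with an estimated correlation. Cytokines and colony-stimulating factors were higher in 11 of 19 and lower in 3, Ltb (−1.15), Tnfsf10 (−0.90) and Il15, or 12 and 3 adjusted over the list alone. Cytokines had a camera adjusted p = 4.41e-05, and adjusted p = 0.155 with an estimated correlation. NF-kappaB pathway genes were higher in 13 of 24, led by Tnfaip2 (2.93) and Nfkbiz (2.69), and lower in 1, Cyld (−0.34), or 16 and 3 adjusted over the list alone. NF-kappaB genes had a camera adjusted p = 4.41e-05, and adjusted p = 0.509 with an estimated correlation. Interferon-induced genes were higher in 16 of 40, led by Mx1 (2.11) and Oasl1 (1.67), and lower in 5, among them Bst2 (−0.29), or 18 and 5 adjusted over the list alone. Interferon-induced genes had a camera adjusted p = 0.0427, and adjusted p = 0.625 with an estimated correlation and 0.0946 with fry. Prostaglandin and nitric oxide synthesis was higher in 8 of 14, with the inducible cyclooxygenase gene Ptgs2 (3.04) and Ptges (2.31), and lower in 2, or 8 and 3 adjusted over the list alone. Prostaglandin and nitric oxide genes had a camera adjusted p = 0.0102, and adjusted p = 0.484 with an estimated correlation. Matrix and matrix proteases were higher in 7 of 22, with Mmp13 (4.89) and Mmp3 (3.50), and lower in none. Matrix genes had a camera adjusted p = 0.0192, and adjusted p = 0.484 with an estimated correlation. The Wnt and beta-catenin barrier programme was lower in 10 of 21, led by Tnfrsf19 (−1.44) and Tcf7 (−1.19), and higher in 2, Lef1 (0.43) and Sox7 (0.40), or 11 and 2 adjusted over the list alone. Wnt genes had a camera adjusted p = 0.0102, and adjusted p = 0.562 with an estimated correlation.

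MHC class I presentation had none of 23 genes higher and 5 lower with IL1B than with TNF, among them Tapbpl (−0.54) and Psmb9 (−0.37), or 4 adjusted over the list alone (camera adjusted p = 0.298). Psmb9 was not called without TNF replicate 2 or 4 or IL1B replicate 1 or 3 (adjusted p = 0.0607 to 0.0742) or with the libraries numbered 2, 4 and 5 alone (adjusted p = 0.226). Costimulatory and coinhibitory ligands were higher in 5 of 11, led by Tnfsf15 (6.20), and lower in 2, Cd83 (−1.36) and Vsir (−0.51), or 6 and 2 adjusted over the list alone (camera adjusted p = 0.0741). Endothelial markers were lower in 6 of 15 and higher in none (camera adjusted p = 0.0121, and adjusted p = 0.974 with an estimated correlation and 0.0568 with fry). The other gene lists did not pass (adjusted p = 0.0580 to 0.929). Counts higher and lower were 6 and 2 of 15 for leukocyte adhesion molecules (7 and 3 adjusted over the list alone), 1 and 0 of 7 for chemokine receptors, 2 and 7 of 22 for junctions (3 and 8), 4 and 7 of 29 for barrier transporters (6 and 9), and 5 and 4 of 22 for caveolae. The signalling and presentation lists had 5 and 4 of 27 for actin machinery, 6 and 3 of 19 for TNF receptor signalling, 6 and 1 of 15 for IL-1 receptor signalling (6 and 2), 0 and 0 of 4 for MHC class II and 4 and 0 of 10 for complement (4 and 2). They were 7 and 2 of 19 for coagulation, 0 and 7 of 15 for Notch, 1 and 3 of 14 for arterial, 4 and 2 of 14 for venous and 2 and 4 of 20 for angiogenic genes. The remaining lists had 7 and 0 of 23 for immediate early genes, 1 and 4 of 27 for cell cycle (0 and 3), 3 and 3 of 17 for cell death, 4 and 0 of 15 for endoplasmic reticulum stress (3 and 0) and 0 and 2 of 19 for sterol synthesis. The median and mean log2 fold change differed in sign for chemokine receptors (−0.04 and 0.18, test upward), venous markers (−0.00 and 0.81, test upward) and cell death regulators (−0.00 and 0.42, test upward). With the replicate block, 4 lists passed that did not without it: costimulatory ligands, Notch and immediate early genes (adjusted p = 0.0473 each) and cell cycle (adjusted p = 0.0382). In the same order they had adjusted p = 0.509, 0.562, 0.562 and 0.704 with an estimated correlation.

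The responses to both cytokines overlapped. Of the called genes 1665 were higher and 1379 lower with both TNF and IL1B than in NS, where independent lists of these lengths would share 518 and 427. Both comparisons use the same NS libraries, and with unchanged groups simulated against those libraries a mean of 0.05 genes were higher with both. Those groups held no changed gene, so hardly any calls could arise. Their count does not show how far shared NS libraries enlarge the overlap. With the NS libraries split in the 10 ways into 2 and 3, 658 to 1021 genes were higher and 389 to 902 lower with both. Fewer NS libraries per test also lower these counts, and the TNF and IL1B libraries still share their numbers. With the replicate block 2404 genes were higher and 2347 lower with both. The log2 fold changes correlated across genes at r = 0.811 (genes are not independent replicates), against 0.505 in simulated unchanged groups and 0.608 to 0.744 with split controls, and their covariance of 0.315 lay 0.295 above that simulated. Of the 1665 genes higher with both, 746 were higher with IL1B than with TNF, 40 were lower and 879 were not told apart, and of the 1379 lower with both 666 were lower with IL1B and 8 higher. A further 2471 genes were called higher with IL1B only, of which 1370 also differed from TNF directly, and 167 were called higher with TNF only, of which 94 were directly lower with IL1B. Opposite calls were rare, with 5 genes higher with TNF and lower with IL1B (Slc29a3, Samhd1, Tmod2, Mettl27 and 1600014C10Rik, named after their values were seen) and 11 the reverse.

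**Figure D3:**
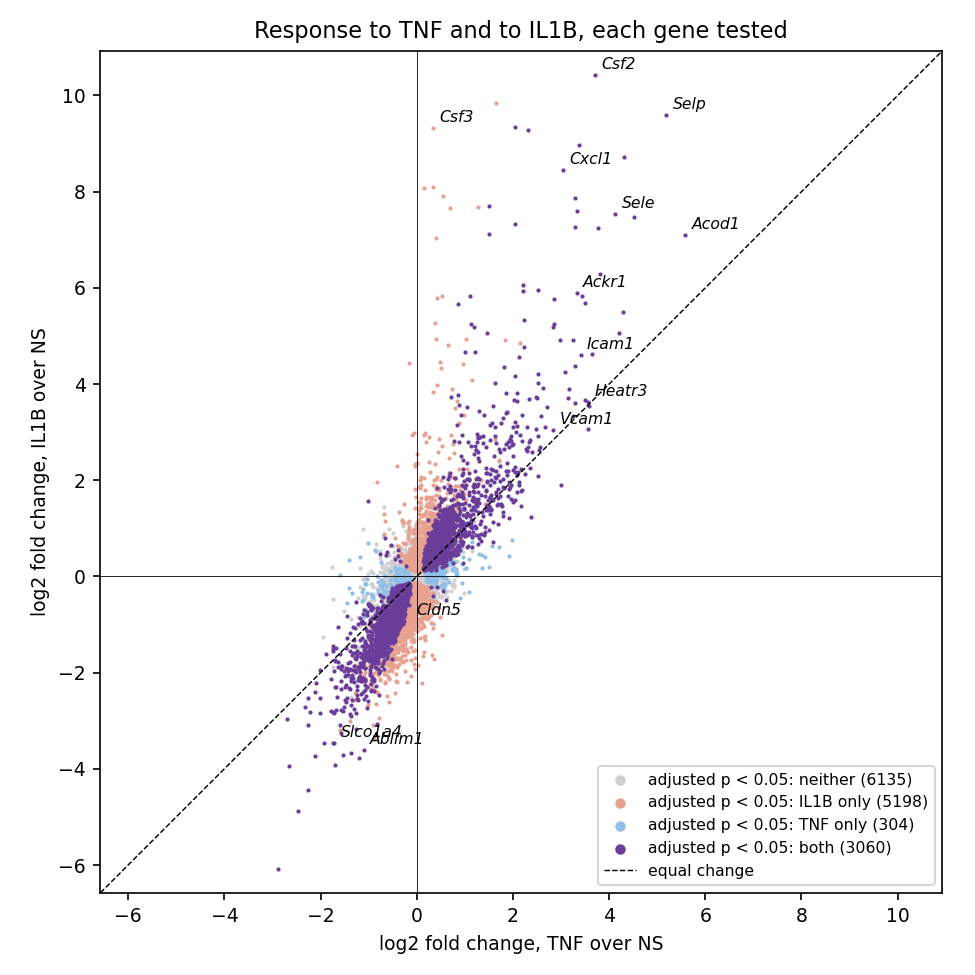
Log2 fold change over NS of each of the 14697 genes tested, TNF on the horizontal and IL1B on the vertical axis, coloured by which comparison called the gene (limma adjusted p under 0.05), with a dashed line of equal change. Ackr1 lies at 3.32 and 5.88, and Selp at 5.19 and 9.59.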

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

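The tests in this part were chosen after the results were seen, apart from the label splits at its end, which were written before. Dixon's test over the 5 libraries of a group was run on every gene named, the marker sums and the library totals. It set a library apart in 48 of 432 sets, where chance gives about 1 in 20, or 21.6. IL1B replicate 5 was the library in 27 of these sets and NS replicate 3 in 11. Values below are the ratio of that library to the median of the other 4.

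In IL1B replicate 5, far from the other IL1B libraries, the genes on the low side were Abcc1 0.496, C3 0.301, Ccrl2 0.481, Csf2 0.412, Csf3 0.208, Ehd1 0.604, Icosl 0.512, Mfsd2a 0.609, Nfkbiz 0.613, Sele 0.182, Src 0.377, Tnfaip2 0.229, Tnfaip3 0.420 and Vcam1 0.583. On the high side were Aif1 4.17, Bach2 2.98, Bcl2 1.85, Cavin2 2.14, Jup 1.90, Kdr 2.29, Lfng 2.31, Ltb 1.79, Pecam1 1.67, Spns2 2.67 and Tnfrsf19 1.91, and the sums of lymphocyte markers (2.20) and mitochondrially encoded transcripts (1.15). In NS replicate 3 the genes above the other NS libraries were C3 4.71, Ccl5 5.06, Csf2 16.8, Cxcl2 1.88, Gbp6 1.57, Icam1 1.83, Radil 3.09, Selp 2.69 and Tapbpl 1.17, and those below were Bcl2 0.698 and Irf8 0.681. Elsewhere the ratios were Apol7c 2.79 in TNF replicate 2, Bcl2 1.31 in TNF replicate 5, Ccl20 12.7 in TNF replicate 3, Kdr 0.800 in NS replicate 2, Mcm2 0.772 in TNF replicate 1, Nos2 1.89 in TNF replicate 2, Steap4 4.64 in TNF replicate 2, Tcf7 1.37 in TNF replicate 5 and Tril 7.51 in TNF replicate 5. Cxcl3 had 0.876 normalised reads in NS replicate 2 and 0 in the other NS libraries. Some large ratios rest on few reads. In NS replicate 3 Csf2 had 7.20 normalised reads against a median of 0.428, and C3 14.4 against 3.06. Ccl20 had 30.3 against 2.39 in TNF replicate 3, and Aif1 32.4 against 7.77 in IL1B replicate 5. Csf2, Ccl5, Ccl20 and Tril also held values uncertain in their trailing zeros, so their ratios may come from the placing.

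The weaker response of IL1B replicate 5 was weighed against 3 technical explanations, and no biological explanation was tested. RNA from unstimulated cells would lower all raised genes by a like factor. This was tested on 41 genes raised at least 8-fold by IL1B. They had at least 5 CPM with IL1B and trailing zeros placed with a posterior of at least 0.95 in all 5 IL1B libraries. Of these, 4 lay at least 2-fold above the median ratio of IL1B replicate 5, 0.532 (Atp2b4 at 2.04), against 0 in each other IL1B library. However, 34 of the 41 were lowest in IL1B replicate 5. Whether the 4 genes also stood apart in the other libraries numbered 5 was not checked, so the explanation is not excluded. A swap with a TNF library is excluded, since 96.6% of 29 genes raised at least 16-fold over TNF lay at least 4-fold above every TNF library. A weaker response of the preparation numbered 5 cannot be told: the response slope of TNF replicate 5 was 0.775 and the next lowest TNF slope 0.851, while IL1B replicate 5 had the lowest slope of its group and the other IL1B libraries 1.04 to 1.09.

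The lower endothelial markers with IL1B were weighed against a smaller share of endothelial cells in those libraries. That would lower all of them alike, but Cdh5 and Erg lay 6.96 and 5.51 standard errors above the median log2 fold change of the list (−0.64). These were the least lowered markers of the list, and the distances count no error of the median. With library-total scaling Cdh5 was itself called lower (−0.23, limma adjusted p = 0.0307), so these genes alone do not exclude it. Over the whole list the distances ran from −7.26 (Slco1a4) to 6.96 (Cdh5). The markers thus did not fall alike, which argues against a smaller share as the sole cause. A smaller share would also raise the marker sums of the cells that took its place. With IL1B the astrocyte sum was 141 ± 10.8 CPM against 87.3 ± 11.6 in NS, and the pericyte and smooth muscle sum 723 ± 526 against 681 ± 509. Fibroblast (124 ± 66.2 against 204 ± 174), microglial and macrophage (32.0 ± 3.59 against 44.2 ± 2.26) and the remaining cell marker sums were lower. The sums went both ways and were not tested. A smaller share as part of the cause, another mix of endothelial subtypes and a change of transcript levels within endothelial cells were not tested, and the cause is left open.

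Whether the calls rest on the group labels was tested by splitting the 10 libraries of each comparison in other ways. Among 100 splits per comparison only the real one, 1 of 100, gave as many genes. TNF against NS had 3364 calls and the highest other split 5. IL1B against NS had 8258, and the highest other, which exchanged IL1B replicate 5 with NS replicate 3, had 5241. IL1B against TNF had 4710, and the highest other, which exchanged IL1B replicate 5 with TNF replicate 3, had 3746. The 1 of 100 comes from splits that mostly do not keep to the pairs. Besides the real one 12, 11 and 11 splits part all 5 same-numbered pairs, in the same order of comparisons. They gave at most 0, 0 and 8 calls, but are too few to give the real split a small share.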

How the results depend on the processing

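No call of a named gene reversed its direction under the alternatives in which it was rerun. In the fits to only both groups compared Ackr1 alone was rerun, and in the 1.5-fold test no named gene was. Gene lists were rerun only with an estimated correlation, the replicate block and fry, and no call of a list reversed there. Library-total scaling turned the larger share of the calls against NS downward (1554 genes higher and 1813 lower with TNF, 2807 and 5631 with IL1B). The near-equal counts of IL1B against NS also tipped downward with TMM (4079 and 4152), no filter (4124 and 4216), the replicate block (4678 and 4749), the 1.5-fold test below and without IL1B replicate 2 (3880 and 3940) or 4 (3840 and 3843). For IL1B against TNF the lower side was larger with library-total scaling, TMM (2325 and 2394), the block, zeros placed within each group (2385 and 2391) and without IL1B replicate 2 (1926 and 1979), 4 (1859 and 1885) or 5 (2950 and 3024). MHC class II for IL1B against NS, not passing either test, was downward with camera and upward with fry. The planned edgeR and DESeq2 alternatives were not run. The deposited unit is not a read count, and limma versions took their place, although recovered reads were at hand and were used with voom. Library-total scaling, pseudocounts, voom, within-group zero placing, leaving out moved and uncertain values, and the libraries numbered 2, 4 and 5 alone were added after the data were seen. Leaving out each library in turn gave 1513–1886 genes higher and 1103–1606 lower for TNF against NS, 3840–4356 and 3786–4301 for IL1B against NS, 1859–2950 and 1821–3024 for IL1B against TNF, and 1376–1913 and 1005–1657 with both. The log2 fold changes of Ackr1 then ranged over 3.18–3.41, 5.74–5.99 and 2.46–2.67, and the correlation of both responses over 0.778–0.821. Library-total scaling gave 1344 genes higher and 3701 lower for IL1B against TNF, since it moves all fold changes downward. The replicate block gave 2702 genes higher and 2647 lower with TNF, 3342 and 3397 for IL1B against TNF, and 2404 and 2347 with both. Same-numbered libraries shared deviations (median r = 0.307), which the block takes out of the error. It kept 3361 of the 3364 calls of TNF against NS in the same direction. For IL1B against NS it kept 8239 of 8258, and for IL1B against TNF 4705 of 4710. A test against a 1.5-fold change, by construction, called fewer: 194 and 39 for TNF against NS, 671 and 750 for IL1B against NS, and 135 and 28 for IL1B against TNF. The libraries numbered 2, 4 and 5 alone, fewer samples, gave 891 and 599 for TNF against NS, 924 and 850 for IL1B against TNF, and 806 and 540 with both. Of the gene lists 14, 15 and 7 passed camera for TNF against NS, IL1B against NS and IL1B against TNF. With an estimated correlation 9, 0 and 0 did, with the replicate block 11 for IL1B against TNF, and with fry 20, 25 and 18, and the cause was not tested. Lists that passed camera and not fry were cell cycle (adjusted p = 0.245) and sterol synthesis (0.0583) for TNF against NS, cell cycle for IL1B against NS (0.0547) and interferon-induced genes for IL1B against TNF (0.0946). Of 364 named values, calls were lost for 81 with the libraries numbered 2, 4 and 5 alone, 23 with moved and uncertain values left out, 13 without the filter, 11 with library-total scaling, 4 with zeros placed within each group, 3 with voom, 1 each with TMM, a pseudocount of 5 and the replicate block, and 0 with a pseudocount of 0.5, and for 0 of 314 with the stricter filter. Calls were gained for 8 with the block, 4 with library-total scaling and 2 with zeros placed within each group. Over each library left out, 175 of 3640 were lost and 2 gained. In simulation 62.8% of genes changed 1.5-fold were called, and depth was not varied.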

Other observations

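The test in this part was chosen after the results were seen. Of the 1837 genes raised by TNF 139 (7.57%) were lower with IL1B than with TNF. Over all 14697 genes tested 2352 were lower, a larger share. Only 9 of the 139 were raised at least 2-fold and then at least 2-fold lower. Among the 139 were Cd83 (0.91 over NS with TNF and −1.36 for IL1B against TNF), Ltb (2.38 and −1.15), Tnfsf10 (1.35 and −0.90), Tapbpl (1.40 and −0.54) and Vsir (1.40 and −0.51). The explanation that IL1B gives the TNF response at a larger size was tested by taking rises from 2 TNF libraries and the comparison with IL1B from the other 3, adjusted over the raised genes alone. Over the 10 ways to part them at least 72 genes, and at most 100, were raised and yet lower with IL1B. The false calls allowed, 1 in 20 of all calls higher or lower among the raised genes, were at most 47.5. This adjustment took the place of one over all genes, with a smaller allowance for false calls, after the earlier count had been seen. Under the earlier adjustment 36 to 78 genes were raised and yet lower with IL1B. The counts argue against the explanation as the sole cause. As the test was changed after they were seen, they do not exclude it. Of 121 genes raised at least 8-fold by IL1B 93 were called higher with TNF, 28 were not called and 0 were lower.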
